A study of Mus musculus with 50 samples.

How the data were processed

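The data were counts of mature miRNAs in blood serum of C57BL/6 mice, for 25 libraries in 5 groups (MCAO, MCAO_Sham, ICH, ICH_Sham and Naive, 5 libraries each). Per the labels' protocols, blood was left to clot, serum was spun again to remove cells and debris, and hemolysis was checked by absorbance. RNA was extracted with miRNeasy kits from 200 µL of serum after a synthetic worm miRNA, cel-miR-39, had been added, and libraries were made with the NEBNext small RNA kit from a fixed volume of input, per the labels' protocols. With a fixed volume, differences in RNA yield may enter the library totals, which was not tested. Sequencing was on an Illumina HiSeq in 2 lanes, per the labels' protocols, which call it paired-end. Bowtie 0.12.9 was used, per the submitters' processing notes. The genome build, the miRNA annotation release, read trimming and the treatment of reads that match several miRNAs are not given in the sources used here.

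The authors deposited 1 table of whole-number counts, not normalized, with 1892 miRNA entries and 50 columns, named by group, replicate and run as in the labels. The 2 columns of a library carry the same index tag in the labels and were treated as repeat runs of it. A chi-square test of the 2 runs over miRNAs with at least 20 counts gave 0.792 to 1.27 per degree of freedom, whereas libraries of 1 group differed by 11.2 or more. Read pairs of the same fragments would differ by less than sampling noise, so the columns were read as separate runs and summed. Of the entries, 967 were at 0 in every run and 925 had a count. The spike-in cel-miR-39 was not among the entries analysed, so no scaling to it was made. In 3 kept entries the names of 2 miRNAs are joined, as in miR-486-5p with miR-3107-5p, and their reads cannot be separated. miR-3473b and miR-3473e had 11633 and 11630 counts, with the same count in 20 of 25 libraries, and were read as 1 signal. Mature miRNAs made from several hairpins, such as miR-1a-3p, miR-9-5p and miR-218-5p, cannot be assigned to one of them. The deposited counts are of reads without molecular identifiers.

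Library totals ranged from 38393 to 315646 counts. The filter was edgeR's filterByExpr with a minimum count of 10, which kept 199 miRNAs with 99.5% of all counts. Libraries were scaled by the trimmed mean of M values (TMM), and one negative binomial model with a mean per group was fitted to all 25 libraries, so that the groups shared the estimate of the spread (20 residual degrees of freedom, median prior degrees of freedom 8.90, common biological coefficient of variation 0.297). Comparisons were tested with edgeR's robust quasi-likelihood test, and p-values were adjusted by the Benjamini-Hochberg method over the 199 miRNAs of a comparison with a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of the F statistic. Software versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.

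There were 7 comparisons. They were MCAO with MCAO_Sham, ICH with ICH_Sham, MCAO_Sham, ICH_Sham, MCAO and ICH each with Naive, and the difference between the effects of MCAO and ICH over their own shams (interaction). Single values per library (totals, shares of counts, the ratio of miR-451a to miR-23a-3p and the members of the Htr2c cluster) were compared by exact two-sided permutation tests over the 252 splits of 5 against 5, whose smallest p is 0.00794, with Benjamini-Hochberg adjustment over each family. Ratios of summed counts have exact 95% intervals. Where a group had 0 counts, a floor of 3 counts over the group was used.

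Before the data were examined, 16 lists of miRNAs were fixed from general knowledge, the first of them with the series' reference to an miRNA cluster in view: the Htr2c intronic cluster, brain-enriched, Dlk1-Dio3 imprinted cluster, muscle, erythrocyte, platelet and myeloid, lymphocyte, liver and gut, pancreas and neuroendocrine, epithelial and skin, choroid plexus and pigment epithelium, vascular and mesenchymal, hypoxia (miR-210), let-7 family, miR-17-92 and paralogous clusters, and Sfmbt2 repeat cluster. The 11 lists with at least 3 kept members were tested with limma's camera on log2 CPM (prior count 2) with a preset correlation of 0.01, again with the correlation estimated, and with fry, which asks whether a list's members move one way on balance and compares with no other miRNAs. The erythrocyte and miR-17-92 lists share miR-92a, miR-25 and miR-363.

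The groups, tests, alternatives and rule for named miRNAs were also set before the data were examined. Per comparison, the rule names the 10 largest rises and the 10 largest falls among miRNAs that passed and had the same sign in every leave-one-out fit, or, where fewer than 5 passed, the 5 with the smallest p. It adds kept members of the Htr2c cluster, miR-210, up to 4 members per list for each stroke model against its sham and up to 2 for other comparisons, the 5 smallest p of the interaction, miR-451a, miR-23a-3p and the 5 most abundant miRNAs. After the data were seen, list members were further limited in the text to those with an unadjusted p under 0.05, beside a few members named for contrast. The members of the Htr2c, hypoxia and choroid plexus lists were tested on their counts wherever the groups compared held at least 10 counts, as 1 family of 36 tests. miR-124-3p, miR-449a-5p and both arms of miR-34b were added to these tests after the data were seen.

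Alternatives were DESeq2's size factors in edgeR, library totals alone, DESeq2's Wald test, limma voom with quality weights, no robust estimation, no count filter, a fit of only the groups compared, the replicate number as a block, each sequencing run alone, removal of the erythrocyte list, the ratio of miR-451a to miR-23a-3p as a covariate, the index tag range as a block (MCAO, MCAO_Sham and Naive), and each library left out in turn. After the data were seen, 3 were added. They left out the 3 libraries with a TMM factor under 0.75 (MCAO 2, ICH_Sham 1 and Naive 2), removed miR-148a-3p and miR-122-5p, or thinned each library to 38393 counts. Where an alternative's own filter dropped miR-1298-5p or miR-34c-5p, they were also fitted there with the miRNAs of the main filter. Counts of calls were also compared with those of 100 splits of the samples.

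The fits were tested on simulated counts for MCAO against MCAO_Sham, with 200 of 925 miRNAs changed, in 20 simulations with a mean of 200.4 miRNAs tested. Of changed and tested miRNAs, 74.3% of 456 with a 2-fold change and 98.5% of 454 with a 4-fold change were called, 0 with the wrong sign, and 0.678% of unchanged ones were called. The list test called 20 of 20 shifted sets and 0 of 20 unshifted ones. The shifted sets held miRNAs changed by construction, so their calls say little about weaker shifts. The simulated counts carried no correlation between miRNAs, whereas the muscle list, for example, had an estimated correlation of 0.60. How often the list test calls unshifted lists with correlated members was therefore not tested.

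Positions are those of hairpin genes of the same name in the GENCODE M21 annotation of GRCm38, matched by name, and say nothing about the build used upstream. Sequences and isoforms of miRNAs were not analysed here.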

Results

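Small RNA sequencing of blood serum gave counts of mature microRNAs (miRNAs) in 5 groups of C57BL/6 mice aged 8 to 12 weeks, with 5 libraries in each group. In the MCAO group a filament closed the left middle cerebral artery for 30 min, a model of ischemic stroke, and blood was taken after 150 min of reperfusion. MCAO_Sham mice had the same operation with no filament placed in the artery. ICH mice received 20 µL of their own blood in the striatum, a model of intracerebral hemorrhage. In ICH_Sham mice the needle was placed and nothing was injected, and Naive mice were left untreated. The labels do not say that each library came from a separate animal, so the p-values measure the spread between these libraries, which may be technical.

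Each library was sequenced in 2 runs. Their counts differed by about the sampling noise (chi-square per degree of freedom 0.792 to 1.27 over the 25 libraries), so the runs were summed and counted as 1 sample. Summed totals ranged from 38393 to 315646 counts per library. They averaged 153952 ± 93573 in MCAO, 92396 ± 53034 in MCAO_Sham, 118431 ± 24159 in ICH, 115325 ± 41509 in ICH_Sham and 55662 ± 23160 in Naive (SD, n = 5 each). The log2 total lay above Naive by 1.39 in MCAO, 1.16 in ICH and 1.08 in ICH_Sham (adjusted p = 0.0476 for each, exact two-sided permutation tests, 6 comparisons), and by 0.67 in MCAO_Sham (adjusted p = 0.210, exact permutation test). Between 337 and 495 miRNAs were detected per library, and 199 passed the filter on low counts. Intervals and floors given here rest on counts summed over a group, so they cover counting error only and not the spread between libraries. The reads carry no molecular identifiers, so PCR copies may make the counting error larger than these intervals show. Unless stated otherwise, values are log2 fold changes with their standard errors (SE) and adjusted p-values from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and levels are CPM (counts scaled to the library size) as mean ± SD with n = 5.

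The most abundant miRNA was miR-148a-3p, with 13.7% of all counts, followed by miR-122-5p, the main miRNA of liver cells, with 8.66%, and by miR-99a-5p, miR-10b-5p and miR-143-3p with 5.49%, 5.16% and 4.41%. The share of miR-148a-3p was 20.8% ± 13.6 in MCAO, 9.14% ± 2.73 in MCAO_Sham, 10.0% ± 3.25 in ICH, 7.44% ± 0.997 in ICH_Sham and 5.32% ± 1.64 in Naive (SD, n = 5). In the library MCAO 2 it reached 43.4%. The share of miR-122-5p was 32.5% in ICH_Sham 1 and 32.4% in Naive 2. The log2 ratio of miR-451a, a red cell miRNA, to miR-23a-3p, which red cells hold little of, is a measure of red cell content. It was -0.69 ± 0.69 in MCAO, -1.60 ± 1.03 in MCAO_Sham, -2.15 ± 0.91 in ICH, -1.93 ± 0.22 in ICH_Sham and -1.35 ± 0.49 in Naive (SD, n = 5), and no comparison of it passed (adjusted p from 0.190 to 0.698, exact permutation tests, 6 comparisons). With miR-486-5p, another red cell miRNA, in place of miR-451a the difference was -0.55 for MCAO against MCAO_Sham (adjusted p = 0.105, exact permutation test) and -0.77 for MCAO against Naive (adjusted p = 0.0238, exact permutation test), opposite in sign to that with miR-451a. It was -0.81 for ICH against ICH_Sham, -0.94 for ICH_Sham against Naive and -1.75 for ICH against Naive (adjusted p = 0.0159 each, exact permutation tests).

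MCAO against MCAO_Sham asks which serum miRNAs differ after ischemia and reperfusion. The largest difference was in miR-1298-5p, which lies in an intron of Htr2c, the gene of the serotonin 2C receptor. It rose by 5.29 ± 0.55 (adjusted p = 3.29e-08), from 33.4 ± 37.0 CPM in MCAO_Sham to 1327 ± 808 CPM in MCAO, and the lowest MCAO library (235 CPM) stood above the highest sham library (84.7 CPM). The other groups held 14.6 ± 10.1 CPM (ICH), 17.2 ± 10.9 CPM (ICH_Sham) and 22.1 ± 16.4 CPM (Naive). Its summed counts were 923 in MCAO and 16 in MCAO_Sham, a CPM ratio of 43.4 with a 95% interval of 26.6 to 76.2. An exact permutation test of the libraries gave p = 0.00794, the smallest that 5 against 5 allows, and adjusted p = 0.0952 over the 36 count tests of the Htr2c, hypoxia and choroid plexus lists. Adjusted over 36 tests, that smallest p passes only if several other tests reach it too, so this adjusted value decides little. The index tags of both groups fell into 2 ranges. Within the lower range miR-1298-5p had 834 counts in MCAO and 13 in MCAO_Sham, a ratio of 41.7, and within the upper range 89 and 3, a ratio of 29.1.

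Htr2c spans chromosome X 146962513 to 147197277 on the plus strand (GENCODE M21 annotation of GRCm38). Its introns also hold Mir764 (147002259 to 147002366), Mir1912 (147009441 to 147009527), Mir1264 (147010601 to 147010686) and Mir448 (147158210 to 147158321), beside Mir1298 (147064905 to 147065002). Of this list, fixed with the series' reference to an miRNA cluster in view and so no independent evidence of its direction, miR-1298-5p alone passed the count filter. miR-448-3p had 97 counts in MCAO and 1 in MCAO_Sham, a CPM ratio of 72.9 with an interval of 12.8 to 2909 (exact permutation p = 0.0476, adjusted p = 0.286). miR-1264-3p had 38 counts against 2, a ratio of 14.3 with an interval of 3.69 to 122 (exact permutation p = 0.0159, adjusted p = 0.143). Both passed in edgeR's quasi-likelihood fit without a count filter, over 925 miRNAs (adjusted p = 9.73e-11 and 0.000879). miR-1298-3p had 12 counts against 0, a CPM 3.01-fold that of a floor of 3 counts over the group, with a lower 95% counting limit of 2.09 for the ratio (exact permutation p = 0.167, adjusted p = 0.623). It passed in the fit without a count filter as well (adjusted p = 0.0258), with 7 of the counts in MCAO 2 and 0 in MCAO 1 and MCAO 5. miR-764 had 0 counts in all 25 libraries, and miR-1912-3p had 1 count, in MCAO. Naive libraries held 1 count of miR-448-3p and 0 of miR-1264-3p, where 3 counts over the group correspond to 10.8 CPM.

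**Figure D1:**
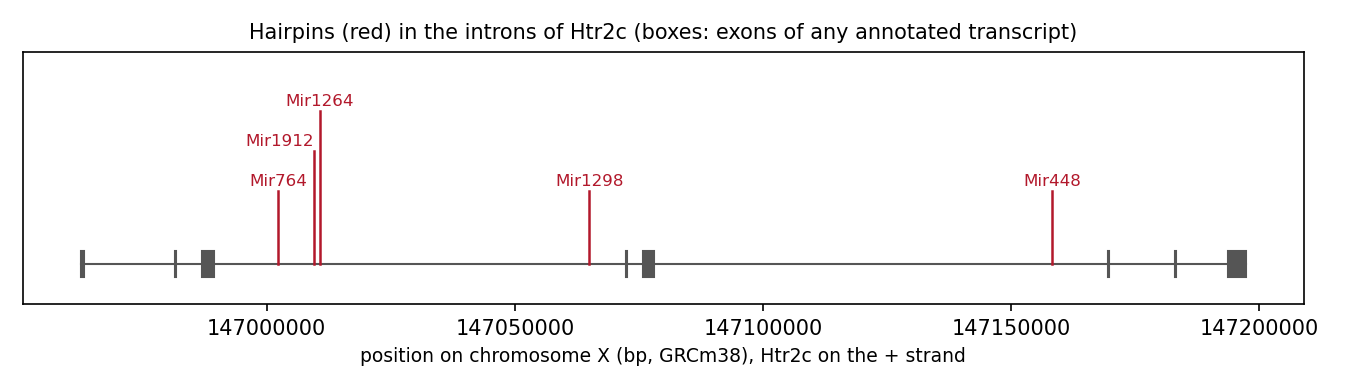
Map of Htr2c on chromosome X (GRCm38, position in bp), with exons of any annotated transcript as grey boxes and the 5 miRNA hairpins as red lines. Mir1298 at 147064905 lies between Mir1264 at 147010601 and Mir448 at 147158210, each within an intron.

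**Figure D2:**
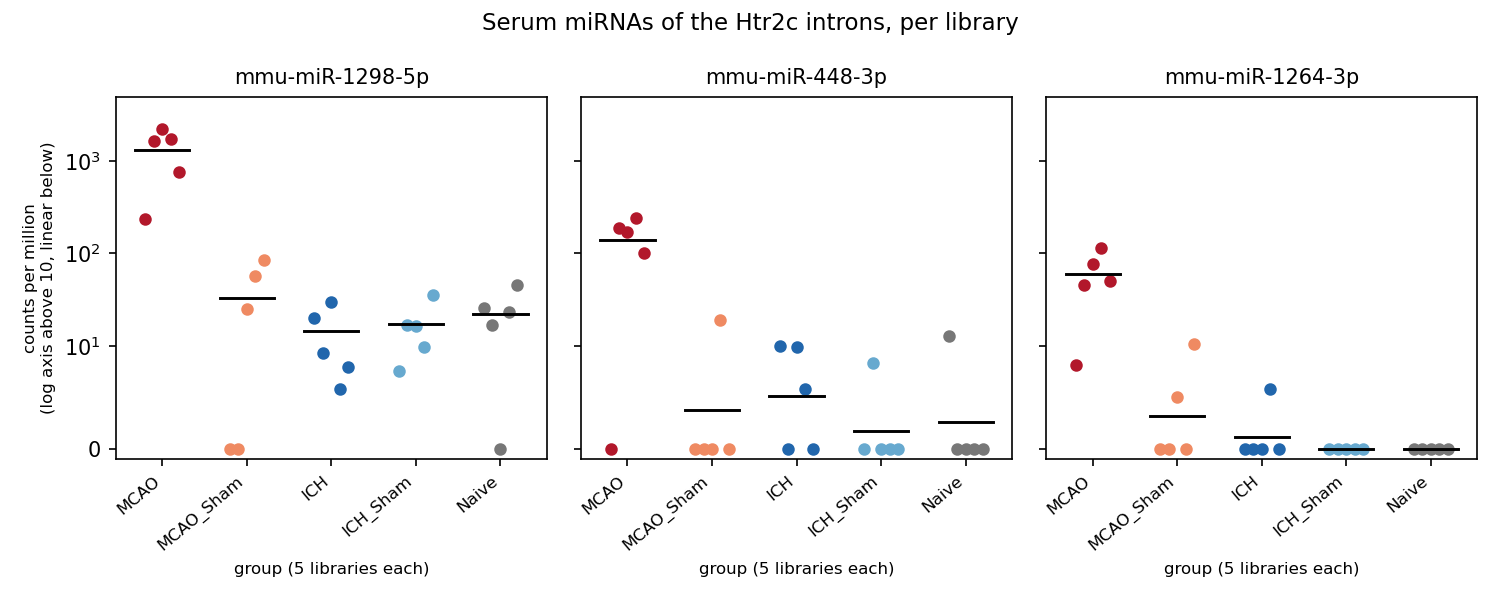
CPM of miR-1298-5p, miR-448-3p and miR-1264-3p in the 25 libraries by group, on a log axis above 10 CPM and a linear one below, with 1 point per library and a line at each group's mean. MCAO libraries of miR-1298-5p lie between 235 and 2232 CPM, above the 84.7 CPM of the highest sham library.

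In all, 15 of 199 miRNAs passed between MCAO and MCAO_Sham, 11 higher and 4 lower, and 66 had an unadjusted p under 0.05. miR-34c-5p, known as a target of p53 (chromosome 9, 51103034 to 51103110, with no gene on its strand), rose by 1.91 ± 0.39 (adjusted p = 0.00307) from 50.9 ± 15.7 to 188 ± 66.1 CPM. miR-218-5p, from introns of Slit2 (chromosome 5) and Slit3 (chromosome 11), rose by 1.38 ± 0.34 (adjusted p = 0.0118). Both arms of miR-148a (chromosome 6, 51269812 to 51269910) rose, the 3p arm by 1.58 ± 0.41 (adjusted p = 0.0162) and the 5p arm by 1.45 ± 0.40 (adjusted p = 0.0187). miR-615-3p, from an intron of the homeobox gene Hoxc5 (chromosome 15, 103014910 to 103015001), fell by 1.64 ± 0.45 (adjusted p = 0.0187) from 310 ± 125 to 103 ± 57.9 CPM. miR-674-3p fell by 0.87 ± 0.21 (adjusted p = 0.0110), and miR-149-5p, from an intron of Gpc1, fell by 0.84 ± 0.26 (adjusted p = 0.0462). miR-1298-5p and miR-34c-5p passed in every fit that left out 1 library, and miR-34c-5p missed the threshold in libraries thinned to 1 depth (1.31, adjusted p = 0.107). Without MCAO 2 these 2 were the remaining calls, with miR-148a-3p at 0.79 (adjusted p = 0.185) and miR-148a-5p at 0.72 (adjusted p = 0.242), while 55 miRNAs passed without MCAO 5, 34 without MCAO_Sham 4 and 24 without MCAO_Sham 2. miR-141-3p, miR-148a-5p, miR-1a-3p, miR-486-5p, miR-615-3p and miR-149-5p also lost their calls without other single libraries. With the index tag range as a block 2 miRNAs passed, and 2 with the ratio of miR-451a to miR-23a-3p as a covariate, whereas DESeq2 called 43 and limma voom 24.

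Of the epithelial and skin list, 3 of 11 measured members rose, and 9 rose when adjusted over the list alone, with a list median of 1.10. The 3 were members of the miR-200 family, which maintains epithelial identity. miR-200a-3p (chromosome 4, 156054896 to 156054985) rose by 1.50 ± 0.34 (adjusted p = 0.00985) from 4441 ± 1848 to 12594 ± 7961 CPM. Its neighbour miR-200b-3p rose by 1.37 ± 0.35 (adjusted p = 0.0137) and miR-141-3p (chromosome 6, 124717914 to 124717985) by 1.67 ± 0.46 (adjusted p = 0.0187), while miR-200c-3p was at 1.10 ± 0.36 (adjusted p = 0.0517). The keratinocyte miRNA miR-203-3p was at -0.16 ± 0.27 (adjusted p = 0.701). In limma's camera test with a preset correlation the list was higher (adjusted p = 0.0145, 11 lists), with adjusted p = 0.773 with an estimated correlation. Its camera test ended without MCAO 2 (adjusted p = 0.0797, list median 0.65, with miR-200b-3p at 0.92, adjusted p = 0.143), MCAO_Sham 4 (0.0582) or MCAO_Sham 5 (0.126).

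The remaining lists did not pass between MCAO and MCAO_Sham. In the let-7 family, let-7g-5p rose by 0.87 ± 0.21 (adjusted p = 0.0110), and adjusted over the list alone 4 of 11 members were higher and 1 lower (camera adjusted p = 0.233). Of the erythrocyte list, 1 of 7 members fell, and 2 when adjusted over the list alone (camera adjusted p = 0.494). That member was miR-486-5p, a red cell miRNA from an intron of Ank1 (chromosome 8, 23142555 to 23142682), listed jointly with miR-3107-5p. It fell by 0.98 ± 0.27 (adjusted p = 0.0187), while miR-92a-3p was at -0.92 ± 0.33 (adjusted p = 0.0578) and miR-451a at 0.30 ± 0.31 (adjusted p = 0.497). Of 5 muscle miRNAs miR-1a-3p rose by 1.18 ± 0.34 (adjusted p = 0.0257), with a list median of 0.23 (camera adjusted p = 0.624). No member passed among 13 of the imprinted Dlk1-Dio3 cluster (median -0.45), 4 brain-enriched (0.17), 7 lymphocyte (-0.37), 13 vascular and mesenchymal (-0.31), 12 platelet and myeloid (-0.10), 5 liver and gut (0.15) and 7 miR-17-92 and paralogous cluster miRNAs (0.16), with camera adjusted p from 0.233 to 0.924. Lists with under 3 kept members were not tested as lists. miR-204-5p, abundant in choroid plexus, was at 0.55 (adjusted p = 0.204), miR-669c-5p of the Sfmbt2 cluster at 0.01, and of 2 pancreas miRNAs 0 passed. The hypoxia marker miR-210-3p stayed under the filter, with 42 counts in MCAO and 26 in MCAO_Sham, a CPM ratio of 1.21 with an interval of 0.727 to 2.06.

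ICH against ICH_Sham asks the same question for hemorrhage. edgeR called 0 of 199 miRNAs, with 20 at an unadjusted p under 0.05 where chance gives 9.95, and a smallest adjusted p of 0.421. DESeq2 called 0 (17 at p under 0.05) and limma voom 0 (19). The smallest p belonged to miR-203-3p, a keratinocyte miRNA (chromosome 12, 112130880 to 112130955), at 0.93 ± 0.28 (14730 ± 8628 CPM in ICH, 7733 ± 914 CPM in ICH_Sham). miR-34c-5p was at 1.36 ± 0.44 (adjusted p = 0.441; 82.1 ± 40.5 against 29.7 ± 13.2 CPM), the lymphocyte miRNA miR-150-5p at -0.69 ± 0.26, miR-615-3p at 1.10 ± 0.42 and miR-6538 at -1.12 ± 0.43 (adjusted p = 0.462 each). Positive values that did not pass were found for the brain-enriched miRNAs miR-9-5p, abundant in neural progenitors (1.54 ± 0.68), miR-129-5p (0.87 ± 0.40) and miR-219a-2-3p, known from oligodendrocytes (1.81 ± 0.85), each with adjusted p = 0.462. miR-1298-5p was at -0.26 ± 0.96 (adjusted p = 0.950), and miR-210-3p had a CPM ratio of 1.24 with an interval of 0.781 to 1.97. Without ICH 4, miR-203-3p passed (1.09, adjusted p = 0.0319). The index tags of ICH and of ICH_Sham each formed a range of their own, so that tags and groups cannot be told apart here, in the ICH part of the interaction, or against Naive.

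The 5 muscle miRNAs were lower in ICH as a list, with a median of -0.47 and 0 members past the threshold (camera adjusted p = 0.0370). With an estimated correlation the list had adjusted p = 0.734. It also missed the threshold without ICH 1, ICH 3, ICH 5, ICH_Sham 1 or ICH_Sham 3 (adjusted p from 0.0958 to 0.298). The epithelial and skin list had a median of -0.05 with 1 of 11 members, miR-203-3p, higher when adjusted over the list alone. Brain-enriched miRNAs had a median of 1.21 (camera adjusted p = 0.357) and the Dlk1-Dio3 cluster one of 0.16 (0.123).

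The difference between the effects of the 2 stroke models, each over its own sham, was tested as an interaction. A time of blood sampling is given here for MCAO alone, so a difference in time cannot be told apart from one between models. It passed for 2 of 199 miRNAs (33 at an unadjusted p under 0.05). miR-1298-5p had a difference of 5.55 ± 1.27 (adjusted p = 0.0148), with an effect of 5.29 in MCAO and -0.26 in ICH. miR-615-3p had one of -2.75 ± 0.62 (adjusted p = 0.0148), with -1.64 in MCAO and 1.10 in ICH. For miR-182-5p, miR-183-5p and miR-200c-3p of the epithelial list, differences of 2.45, 2.58 and 1.56 did not pass (adjusted p = 0.0717, 0.137 and 0.137). Without ICH_Sham 3, 0 miRNAs passed, without ICH_Sham 5 miR-1298-5p did not, and without MCAO 5, 7 passed. With run 2 alone, the red cell ratio as covariate, thinned libraries or without the 3 libraries of low TMM factor, 0 passed. The filter had dropped miR-1298-5p from the thinned libraries, so its interaction was not tested there. Of 100 splits of the libraries, the real one included, 7 gave at least 2 calls, so chance is not excluded. The epithelial list (median 1.42, 0 of 11 called, and 6 higher and 2 lower when adjusted over the list alone) and the Dlk1-Dio3 list (median -0.53, 0 called) each had camera adjusted p = 0.00940. With an estimated correlation the adjusted p was 0.534 for both. Without ICH 2 or MCAO_Sham 5 the epithelial list missed the threshold (adjusted p = 0.0551 and 0.0571), and without MCAO_Sham 1 the Dlk1-Dio3 list did (0.0557). Across the 199 miRNAs, which are not independent replicates, the 2 effects had a Pearson correlation of 0.11 (jackknife SE 0.217, and 0.0706 to 0.279 with 1 library left out) and a Spearman correlation of 0.22, and 11 of the 15 MCAO calls had the same sign in ICH.

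**Figure D3:**
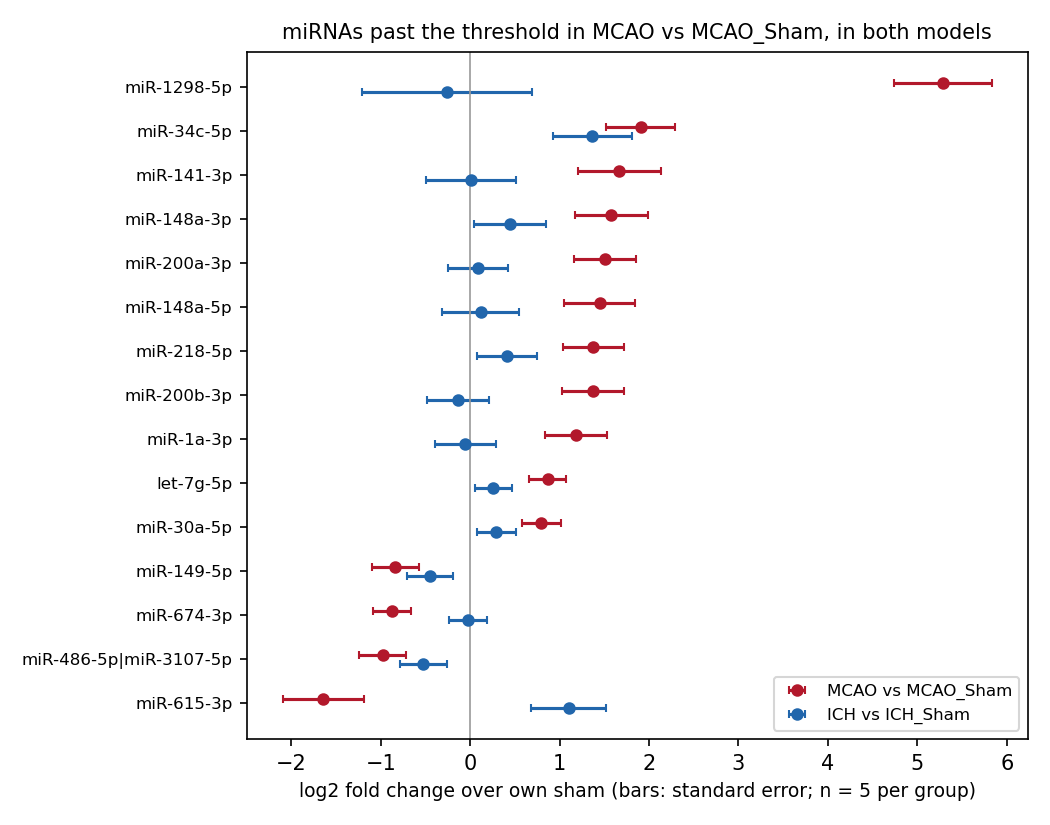
Log2 fold change of each stroke model over its own sham for the 15 miRNAs that passed between MCAO and MCAO_Sham, with bars of 1 standard error (n = 5 per group). miR-1298-5p stands at 5.29 in MCAO and -0.26 in ICH, and miR-615-3p at -1.64 and 1.10.

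The sham groups against Naive show what surgery alone went with, in MCAO_Sham and ICH_Sham. miR-150-5p, a miRNA of mature lymphocytes (chromosome 7, 45121757 to 45121821), fell in both, from 12855 ± 3928 CPM in Naive to 5857 ± 1905 CPM in MCAO_Sham (-1.13 ± 0.26, adjusted p = 0.0332) and 5779 ± 798 CPM in ICH_Sham (-1.15 ± 0.26, adjusted p = 0.00752). In MCAO_Sham it was the single call of 199 miRNAs (18 at an unadjusted p under 0.05), and DESeq2 and limma voom called this 1 miRNA as well. That call was lost without MCAO_Sham 1, 2 or 5 or Naive 5, where 0 miRNAs passed, and 2 passed without Naive 1. It was also lost with the index tag range as a block (-1.26, adjusted p = 0.0884) and with library totals alone (-1.10, adjusted p = 0.137), where 0 passed in each, while its value stayed between -1.34 and -0.99 in these fits and in those that left out 1 library. In ICH_Sham 13 miRNAs passed, 7 higher and 6 lower (34 at an unadjusted p under 0.05). ICH_Sham and Naive libraries share no index tag range, so for these calls and lists tags and groups cannot be told apart. Naive tags also lay outside those of MCAO_Sham, and the tag block set Naive 1 alone among the lower tags. For MCAO_Sham the block therefore separates tags from groups only in part.

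In ICH_Sham the muscle miRNAs miR-133b-3p (chromosome 1, 20682769 to 20682887) and miR-1a-3p rose by 1.92 ± 0.45 (adjusted p = 0.00795; 358 ± 135 to 1370 ± 542 CPM) and 1.37 ± 0.35 (adjusted p = 0.0103; 8206 ± 3066 to 21157 ± 4712 CPM). Of the 5 muscle miRNAs 2 rose, and 4 when adjusted over the list alone, with a median of 1.37 (camera adjusted p = 0.000534). With an estimated correlation the muscle list had adjusted p = 0.1199. miR-199a-3p, a mesenchymal miRNA listed jointly with miR-199b-3p, rose by 0.84 ± 0.20 (adjusted p = 0.00815), miR-708-3p, from an intron of Tenm4, by 1.02 ± 0.25 (adjusted p = 0.00815) and miR-152-3p, from Copz2, by 0.90 ± 0.27 (adjusted p = 0.0349). miR-3473b and miR-3473e, which had the same count in 20 of 25 libraries and were read as 1 signal, fell by 1.42 ± 0.32 (adjusted p = 0.00752; 9370 ± 2685 to 3503 ± 507 CPM). Of 7 miRNAs of the miR-17-92 and paralogous clusters, known to promote cell proliferation, 2 fell, and 4 when adjusted over the list alone. The 2 were miR-106b-3p, of a paralogous cluster (by 0.94 ± 0.25, adjusted p = 0.0175), and miR-19b-3p (by 0.88 ± 0.26, adjusted p = 0.0349). That list was lower (camera adjusted p = 0.000531, adjusted p = 0.0306 with an estimated correlation). The erythrocyte list was lower too, with 1 of 7 members called, miR-486-5p (-0.89 ± 0.27, adjusted p = 0.0349), and 4 when adjusted over the list alone (camera adjusted p = 0.000534, adjusted p = 0.1199 with an estimated correlation). The 2 lists share miR-92a-3p and miR-25-3p, and the log2 ratio of miR-451a to miR-23a-3p lay 0.59 lower in ICH_Sham than in Naive (exact permutation p = 0.0317, adjusted p = 0.190). miR-106b-3p lost its call without ICH_Sham 1 or Naive 3, 4 or 5, and so did miR-152-3p, miR-486-5p and miR-19b-3p. miR-152-3p, miR-486-5p and miR-19b-3p were also lost without ICH_Sham 2, miR-486-5p and miR-19b-3p without ICH_Sham 4, and miR-19b-3p without ICH_Sham 5 or Naive 1 or 2. Under other alternatives, the replicate block aside, miR-19b-3p kept its call in 6 of 14 and miR-486-5p in 9 of 13. miR-708-3p kept it in 10 of 14, miR-106b-3p in 11 of 14 and miR-133b-3p in 13 of 14. miR-708-3p missed the threshold without a filter, in run 2 alone, thinned and without the 3 libraries of low TMM factor.

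The imprinted Dlk1-Dio3 cluster of chromosome 12 was higher than Naive as a list in both sham groups. In MCAO_Sham 12 of its 13 members had positive values with a median of 0.83, 0 passed over all miRNAs and 8 when adjusted over the list alone (camera adjusted p = 5.22e-08, adjusted p = 0.0343 with an estimated correlation). Examples were miR-543-3p at 1.28 ± 0.41, miR-134-5p at 1.08 ± 0.35 and miR-379-5p at 1.03 ± 0.33 (adjusted p = 0.191 each). In ICH_Sham 2 rose, miR-434-3p (109594506 to 109594599) by 1.19 ± 0.27 (adjusted p = 0.00752; 427 ± 137 to 962 ± 176 CPM) and miR-379-5p (109709060 to 109709125) by 1.29 ± 0.32 (adjusted p = 0.00840; 0.83 in run 1 alone, adjusted p = 0.291), and 3 when adjusted over the list alone, with a median of 0.50 (camera adjusted p = 0.000531). With an estimated correlation the list had adjusted p = 0.1199 in ICH_Sham. In MCAO_Sham the lymphocyte list was lower as well (7 members, 1 fell, median -0.31, camera adjusted p = 0.0170), with adjusted p = 0.139 with an estimated correlation. It missed the threshold without MCAO_Sham 1 or 5 or Naive 2 (adjusted p = 0.0705, 0.0501 and 0.0601). Brain-enriched miRNAs had a median of 1.17 (camera adjusted p = 0.146) and liver and gut miRNAs one of -0.53 (0.0502) in MCAO_Sham.

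The effects of the 2 sham operations over the same Naive libraries had a Pearson correlation of 0.612 across miRNAs, which are not independent replicates. Simulated unchanged groups against those Naive libraries gave a median of 0.571 (0.348 to 0.710 over 100 simulations), and the covariance was 0.153 against a simulated 0.0746, a difference of 0.0789. With the Naive libraries split between the comparisons the correlation was 0.0186 to 0.422 (median 0.273, 20 splits). The 1 call that both shared, miR-150-5p, compares with 0 in the simulations and 0.0302 for independent lists. The same sign was seen in 74.4% of miRNAs against a simulated 68.3%. The Dlk1-Dio3 list was called higher in both comparisons in 0 of the 100 simulations, which draw miRNAs independently of each other, and both medians were above 0 in 31. With the Naive libraries split, its medians were 0.47 to 1.17 in MCAO_Sham and 0.18 to 1.03 in ICH_Sham.

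**Figure D4:**
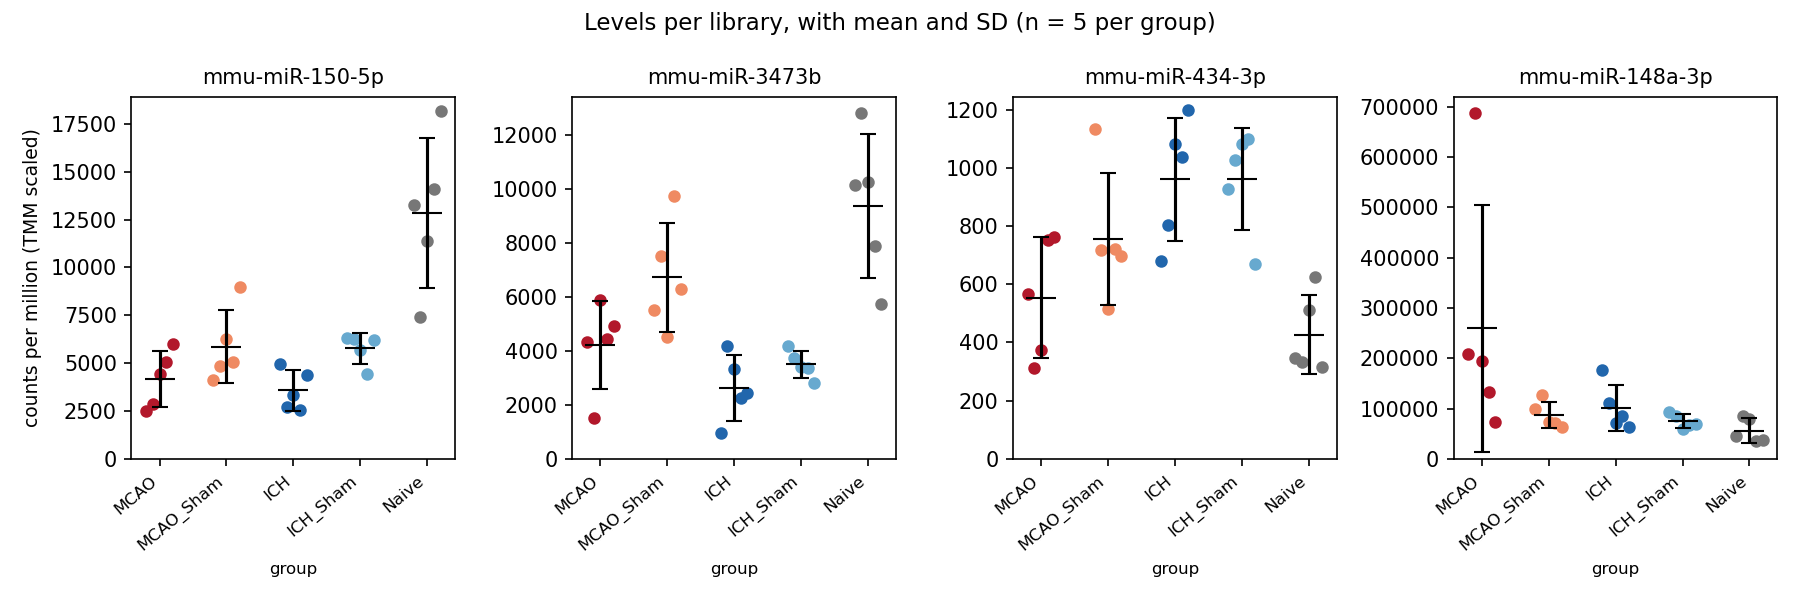
TMM-scaled CPM of miR-150-5p, miR-3473b, miR-434-3p and miR-148a-3p per library, with each group's mean and SD (n = 5). miR-150-5p averaged 12855 in Naive against 3582 to 5857 in the 4 operated groups.

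Against Naive, MCAO differed in 61 of 199 miRNAs, 35 higher and 26 lower (83 at an unadjusted p under 0.05), and ICH in 29, 17 higher and 12 lower (57 at an unadjusted p under 0.05). ICH and Naive libraries share no index tag range either, so for the calls and lists of ICH tags and groups cannot be told apart. miR-150-5p fell by 1.63 ± 0.27 in MCAO (adjusted p = 0.000109) and by 1.84 ± 0.27 in ICH (adjusted p = 2.77e-05). The red cell miRNA miR-486-5p fell by 1.31 ± 0.27 and 1.42 ± 0.27 (adjusted p = 0.000839 and 0.000384), and miR-3473b by 1.16 and 1.83 (adjusted p = 0.00966 and 0.000190). The muscle miRNA miR-1a-3p rose by 1.32 in MCAO and 1.31 in ICH (adjusted p = 0.00784 and 0.00993), the latter lost without ICH 4. miR-9-5p, enriched in brain, rose by 3.27 ± 1.06 and 3.38 ± 1.04 (adjusted p = 0.0254 and 0.0279), from 17.2 ± 30.1 CPM in Naive to 164 ± 86.1 and 161 ± 185 CPM. It lost the call without Naive 1 or 5, and also without MCAO 3 and ICH 4, respectively. The count fell to 25 without MCAO 2, 36 without MCAO 3 and 23 with the index tag range as a block in MCAO, and in ICH to 15 without ICH 4, 17 without Naive 5, and 19 without ICH 2 or without Naive 4.

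In MCAO, miR-1298-5p rose by 5.81 ± 0.64 over Naive (adjusted p = 1.05e-07), and miR-1264-3p had a CPM 5.14-fold that of a floor of 3 counts over the Naive group, with a lower 95% counting limit of 3.98 for the ratio (exact permutation p = 0.00794, adjusted p = 0.0952). Of the epithelial list 7 of 11 members rose, and 9 when adjusted over the list alone, with a median of 1.61. Examples were miR-141-3p at 2.18 ± 0.55 (adjusted p = 0.00558), miR-200a-3p at 1.99 ± 0.35 (adjusted p = 0.000279) and miR-200c-3p at 1.63 ± 0.37 (adjusted p = 0.00218). The list was higher (camera adjusted p = 0.00355, adjusted p = 0.387 with an estimated correlation). Of 7 lymphocyte miRNAs 3 fell (miR-150-5p, miR-181a-5p and miR-181b-5p) and 1 rose (miR-181d-5p, by 0.64), and adjusted over the list alone 5 fell and 1 rose (camera adjusted p = 0.0419, adjusted p = 0.387 with an estimated correlation). The call of miR-181a-5p (-0.56 ± 0.18) was lost without MCAO 2 or Naive 2. This list missed the threshold without MCAO 1 or 5 or Naive 1, 2 or 4 (adjusted p from 0.0551 to 0.0984). miR-148a-3p rose by 2.20 ± 0.42 (adjusted p = 0.000471; 1.41 without MCAO 2, adjusted p = 0.00402), miR-218-5p by 1.96 (adjusted p = 0.000803) and miR-34c-5p by 1.81 (adjusted p = 0.00323). The Dlk1-Dio3 list did not pass by camera in MCAO against Naive (adjusted p = 0.145, adjusted p = 0.563 with an estimated correlation) but passed by fry (adjusted p = 0.0433). It had positive values in 9 of 13 members, 3 that rose, 0 when adjusted over the list alone and a median of 0.38. miR-199a-5p fell by 1.54 (adjusted p = 0.00103), miR-92a-3p by 1.33 (adjusted p = 0.00558) and miR-351-5p by 1.21 (adjusted p = 0.00323).

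In ICH, the Dlk1-Dio3 list was higher than Naive, with positive values in 13 of 13 members, 5 that rose, 5 when adjusted over the list alone and a median of 0.61 (camera adjusted p = 9.50e-05, adjusted p = 0.162 with an estimated correlation). miR-379-5p rose by 1.44 ± 0.31 (adjusted p = 0.00166), miR-300-3p by 1.38 ± 0.33 (adjusted p = 0.00435) and miR-434-3p by 1.19 ± 0.27 (adjusted p = 0.00273). The epithelial miRNAs that rose in ICH were miR-205-5p (1.84 ± 0.40, adjusted p = 0.00166; 1.10 without ICH 3, adjusted p = 0.0114) and miR-203-3p (1.37 ± 0.28, adjusted p = 0.000932), while miR-200a-3p was at 0.36 ± 0.34 (adjusted p = 0.519). miR-199a-3p rose by 1.17 ± 0.21 (adjusted p = 0.000190), miR-708-3p by 1.34 ± 0.24 (adjusted p = 0.000238) and miR-152-3p by 1.28 (adjusted p = 0.00119). Of the erythrocyte list 2 of 7 members fell, and 3 when adjusted over the list alone (camera adjusted p = 0.00621, adjusted p = 0.166 with an estimated correlation). Of the miR-17-92 list 2 of 7 fell, and 3 when adjusted over the list alone (camera adjusted p = 0.0190, adjusted p = 0.162 with an estimated correlation). The latter missed the threshold without ICH 3 or Naive 1 or 2 (adjusted p = 0.0546, 0.0571 and 0.0651).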

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

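The tests of the Htr2c miRNAs, the epithelial list and the Dlk1-Dio3 list were chosen only after those results were seen, while the counts over other splits of the samples were planned.

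In 7 of 155 groups of 5 libraries 1 library stood apart from the other 4, where chance gives 7.75 (1 in 20). The measure is the gap to the nearest library divided by the range of the group, with a limit of 0.71. The log2 TMM factor was lowest in MCAO 2 (0.729) and in ICH_Sham 1 (0.814), and ICH_Sham 1 also had the highest share of miR-122-5p in its group (0.823). The log2 CPM of miR-106b-3p was highest in ICH 1 (0.719) among ICH libraries and lowest in Naive 1 (0.881) among Naive libraries. miR-141-3p was highest in MCAO_Sham 2 (0.818) and miR-3473b lowest in MCAO 2 (0.775).

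The effects of the 2 stroke models over their own shams differed, by the interaction test, by 5.55 for miR-1298-5p and by -2.75 for miR-615-3p on the log2 scale (adjusted p = 0.0148 each, edgeR's quasi-likelihood test). Both calls were absent with run 2 alone, the red cell ratio as covariate or without the 3 libraries of low TMM factor. In thinned libraries that of miR-615-3p was absent, while miR-1298-5p was dropped by the filter and its interaction was not tested. Chance is not excluded either, since 7 of 100 splits gave at least 2 calls.

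Beside miR-1298-5p, the miRNAs miR-448-3p and miR-1264-3p, which stayed under the count filter, had 97 and 38 counts in MCAO, above 1 and 2 counts in MCAO_Sham and 1 and 0 in Naive. The summed counts of the 3 miRNAs had a log2 ratio of MCAO to MCAO_Sham of 5.37 within the lower tag range (956 against 15 counts). It was 4.64 within the upper one (102 against 4). Most of these were counts of miR-1298-5p. For it they argue against the tag range as the whole cause of the difference between MCAO and MCAO_Sham. Its counts came mostly from the lower range in both groups. They were 834 from 3 libraries against 89 from 2 in MCAO, and 13 from 2 libraries against 3 from 3 in MCAO_Sham. Whether its level differs between the tag ranges was not tested. In the upper range miR-448-3p had 8 counts against 1 (interval 1.05 to 348) and miR-1264-3p 5 against 0 (lower limit 0.897). Their other MCAO counts, 89 and 33, came from the lower range, so these 2 decide little by themselves. After thinning to 1 depth miR-1298-5p had a log2 fold change of 6.27 (adjusted p = 1.21e-08, edgeR). Random thinning keeps the expected share of each miRNA, so a difference of this size could hardly be lost. Differences in RNA yield behind the depth were not tested. RNA from neuron-rich brain tissue cannot be told apart from other sources, since miR-124-3p, abundant in neurons, had too few counts (12 against 6, a ratio of 1.50 with an upper limit of 4.88) and miR-9-5p was at 1.44 ± 0.71 (adjusted p = 0.149, edgeR), nor can RNA from choroid plexus, since miR-204-5p, abundant there, was at 0.55 (adjusted p = 0.204) over a high level in the sham group (490 ± 182 CPM, against 728 ± 318 CPM in MCAO, SD, n = 5), and the ischemia that sets MCAO apart stays open as the biological explanation.

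The epithelial and skin list was higher in MCAO than in MCAO_Sham, with a median log2 fold change of 1.10 (SE over members 0.26), by camera with a preset correlation (adjusted p = 0.0145), a call lost with an estimated one (adjusted p = 0.773 with an estimated correlation) and with fry (adjusted p = 0.0818). With miR-148a-3p and miR-122-5p removed the median was 1.12 (SE 0.26). TMM scaling already allows for counts taken up by a few abundant miRNAs. The median could therefore hardly change, and this removal decides little about such counts. With the index tag range as a block the median was 1.003 (SE 0.25), above 0.5 of the full value. These SE take members as independent, although their estimated correlation was 0.36, and do not measure the spread between libraries. The block therefore does not settle a part played by the tag range. A part played by the single library MCAO 2 cannot be told apart from the group, since without it the median was 0.65 (SE 0.19), within its error of 0.5 of the full value. The operation with the filament in place stays open beside it.

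The Dlk1-Dio3 list was higher in both sham groups than in the same Naive libraries by camera with a preset correlation, a call that was kept in MCAO_Sham with an estimated one (adjusted p = 0.0343) and lost in ICH_Sham (adjusted p = 0.1199 with an estimated correlation). By fry, which compares with no other miRNAs, it passed in both (adjusted p = 0.00404 in MCAO_Sham and 0.00825 in ICH_Sham). After thinning to 1 depth the lower of both sham medians was 0.68 (SE 0.14). Random thinning keeps the expected share of each miRNA, so differences in RNA yield behind the depth were not tested. For MCAO_Sham the median was 0.72 (SE 0.15) with the ratio of miR-451a to miR-23a-3p as a covariate, from 0.83 without it. That argues against red cell content as the whole cause, as far as this ratio measures it. For ICH_Sham red cell content cannot be told apart from the operation, since the median was 0.43 (SE 0.19), from 0.50. Its error reaches under 0.5 of the value without the covariate. These SE take members as independent, although their estimated correlation was 0.24, and do not measure the spread between libraries. The sham operation itself stays open as the biological explanation. In MCAO mice, which were operated on too, the list had a median of 0.38 over Naive. It did not pass there by camera (adjusted p = 0.145) but did by fry (adjusted p = 0.0433), so MCAO against Naive stays undecided. Between MCAO and MCAO_Sham the list did not pass (-0.45, camera adjusted p = 0.233).

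Counts of calls were set beside those of 100 splits of the same libraries, the real one included. For MCAO against MCAO_Sham, 4 splits gave at least the real 15 calls, a share under 0.05. That share was not adjusted over the 7 comparisons, so by itself it does not exclude chance. The highest of the other splits gave 51, several times the real count, which points to a structure of the samples. The larger splits, with 18, 37 and 51 calls, exchanged MCAO 5 for MCAO_Sham 5, 2 and 4, and a split by index tag range gave 3 calls (36 at an unadjusted p under 0.05). Against Naive, 2 splits gave at least the real 61 calls for MCAO (highest other 63, with MCAO 5 exchanged for Naive 2). For ICH 1 split gave the real 29 (highest other 20), and for ICH_Sham 1 gave the real 13 (highest other 1). By these shares, likewise not adjusted, chance is argued against for these comparisons. It cannot be excluded for MCAO_Sham against Naive, where 6 splits gave at least the 1 real call (highest other 3), or for the interaction, where 7 gave at least the 2 real calls (highest other 10). For ICH against ICH_Sham the 0 real calls of edgeR (20 at an unadjusted p under 0.05, 0 by DESeq2 and limma voom) are reached by any split, 100 of 100 (highest other 1), so the count decides nothing there.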

How the results depend on the processing

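The alternatives without the 3 libraries of low TMM factor, without miR-148a-3p and miR-122-5p, with thinned libraries, and with the miRNAs of the main filter where a setting's own filter dropped a miRNA were chosen only after the data were seen, and the others were planned. Among the named calls between MCAO and MCAO_Sham, miR-1298-5p kept its call in 15 of 15 alternatives, the replicate block aside, and in 10 of 10 fits that left out 1 library (4.81 to 6.27), and miR-34c-5p in 14 of 15 and 10 of 10 (1.31 to 2.09). The filter dropped miR-1298-5p from run 1 alone and from the thinned libraries, and miR-34c-5p from each run alone, the tag block and the thinned libraries, so there both were fitted with the miRNAs of the main filter. In thinned libraries miR-1298-5p was then at 6.27 (adjusted p = 1.21e-08, edgeR) and miR-34c-5p at 1.31 (adjusted p = 0.107, edgeR), which missed the threshold, and with the tag block miR-34c-5p was at 1.86 (adjusted p = 0.0123, edgeR). The fall of miR-150-5p kept its call in 15 of 15 alternatives and 10 of 10 left-out fits for MCAO against Naive, and in 14 of 14 and 10 of 10 for ICH and for ICH_Sham against Naive. With DESeq2's size factors the counts were 16, 0, 1, 13, 66, 30 and 2, in the order MCAO and ICH against their shams, MCAO_Sham, ICH_Sham, MCAO and ICH against Naive, and the interaction. Where a result did not keep its side of the threshold, the cause was not tested, beyond the fewer libraries, counts or miRNAs that an alternative leaves by construction.

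Between MCAO and MCAO_Sham the 15 calls became 5 with library totals alone, 43 with DESeq2, 24 with limma voom, 29 without robust estimation, 25 without a filter, 23 with the erythrocyte list removed and 29 with miR-148a-3p and miR-122-5p removed. There were 2 calls with only the groups compared, with the red cell ratio as covariate, with the index tag range as a block and without the 3 libraries of low TMM factor. The split into higher and lower was 11 and 4 by the main test, 4 and 1 with library totals, 24 and 19 with DESeq2 and 12 and 12 with limma voom. MCAO_Sham against Naive (1 call) gave 0 with library totals or the tag block. ICH_Sham against Naive (13) gave 22 with limma voom, and library totals moved its 7 higher and 6 lower to 8 and 4. MCAO against Naive (61) gave 27 with library totals, 21 with only the groups compared, 40 with run 1 alone, 30 with the covariate, 23 with the tag block, 32 without the 3 libraries and 33 thinned. ICH against Naive (29) gave 44 with the covariate and 18 thinned, and library totals gave 17 higher and 4 lower in place of 17 and 12. The interaction (2) gave 1 with run 1 alone and 0 with run 2 alone, the covariate, without the 3 libraries or thinned. With run 1 alone and thinned, miR-1298-5p was dropped by the filter, so its interaction was not tested in these. The 1 call shared by both sham groups against Naive became 0 with library totals.

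Called lists between MCAO and MCAO_Sham (1) became 3 without a filter and 0 without the 3 libraries, with an estimated correlation or with fry. For ICH against ICH_Sham (1) there were 0 without a filter, without the 3 libraries, thinned, with an estimated correlation or with fry. For MCAO_Sham against Naive (2) and ICH_Sham against Naive (4) there was 1 with an estimated correlation. By fry, which compares with no other miRNAs, the lists called in these 2 comparisons kept their calls (adjusted p from 0.000729 to 0.0398). MCAO against Naive (2) gave 0 without the 3 libraries or with an estimated correlation, 1 thinned and 5 with fry. ICH against Naive (3) gave 1 with the erythrocyte list removed and 0 with an estimated correlation. The interaction (2) gave 4 without a filter, 1 thinned and 0 with an estimated correlation or fry.

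Library totals alone moved the median log2 fold change of all miRNAs by -0.19 for MCAO against MCAO_Sham, 0.11 for MCAO_Sham against Naive and -0.22 for the interaction, and no filter moved it by 0.14 for MCAO and 0.13 for ICH against Naive. With miR-486-5p in place of miR-451a the red cell ratio was -0.55 for MCAO against MCAO_Sham and -0.77 for MCAO against Naive (adjusted p = 0.0238, exact permutation test), opposite in sign to that with miR-451a, and it was -0.81 for ICH against ICH_Sham, -0.94 for ICH_Sham against Naive and -1.75 for ICH against Naive, each past the threshold (adjusted p = 0.0159, exact permutation tests). The value of miR-1298-5p in ICH against ICH_Sham turned to 0.11 in run 2 alone, and ranged from -0.65 to 0.045 with 1 library left out (above 0 without ICH_Sham 5).

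With the replicate number as a block, calls were 2 for MCAO against MCAO_Sham (1 of them, miR-1298-5p at 5.90, shared with the fit without it, while miR-34c-5p was at 1.75, adjusted p = 0.0538 by edgeR), 3 for MCAO_Sham against Naive, 25 for ICH_Sham against Naive (13 without it), 34 for MCAO against Naive and 1 for the interaction, and called lists 0 for ICH against ICH_Sham, 4 for MCAO_Sham against Naive and 1 for MCAO against Naive. The numbers did not pair the samples: correlations of same-numbered libraries ranged from -0.281 to 0.369 over the 6 comparisons, not every pair of any comparison was over 0.1 (for ICH_Sham against Naive 4 of 5 were, from 0.0190 to 0.263 over all 5), and between 0 and 2 libraries per comparison correlated best with their own number.

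Leaving out 1 library gave 2 to 55 calls for MCAO against MCAO_Sham, 0 to 1 for ICH against ICH_Sham, 0 to 2 for MCAO_Sham, 9 to 16 for ICH_Sham, 25 to 73 for MCAO and 15 to 40 for ICH against Naive, and 0 to 7 for the interaction. The lowest and highest came without MCAO 2 and without MCAO 5 for both MCAO comparisons. In the same order called lists ranged from 0 to 1, 0 to 1, 1 to 3, 4 to 4, 1 to 3, 2 to 3 and 1 to 3, and calls shared by both sham groups from 0 to 2. The correlation of the effects of both stroke models ranged from 0.0706 to 0.279. The red cell ratio ranged from -0.491 to 0.156 for MCAO_Sham against Naive (above 0 without MCAO_Sham 1), from -0.397 to 0.104 for ICH against ICH_Sham (above 0 without ICH 3) and from -0.706 to -0.384 for ICH_Sham against Naive.

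Under alternatives other than a left-out library, named values kept direction and side of the threshold in 287 cases, missed it in 80 and newly passed in 26 for MCAO against MCAO_Sham, with 377, 89 and 5 for MCAO against Naive, 331, 41 and 9 for ICH against Naive and 232, 22 and 14 for ICH_Sham against Naive. Scaling to the spike-in was not run, since cel-miR-39 was not among the entries analysed, and no pseudocount alternative applied to a test on counts. Naive libraries were the shallowest group, and miRNAs under the filter there rest on few counts.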

Other observations

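The tests of miR-124-3p and miR-34b were chosen only after their counts were seen, while the test of hairpin arms was planned.

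miR-124-3p, among the most abundant miRNAs of neurons, stayed under the count filter. It had 0 counts in the 5 Naive libraries and was found in 5 of 5 libraries of MCAO (12 counts), ICH (27) and ICH_Sham (58), and in 3 of 5 of MCAO_Sham (6). It was singled out for these counts, so no test against Naive is given. Naive libraries were also the shallowest, 3 counts over that group correspond to 10.8 CPM, and the counting interval of the ratio of MCAO to Naive reached down to 1.13. Of the ICH_Sham counts 51 came from ICH_Sham 4, and of the ICH counts 15 came from ICH 4, so no fold is given. Between each stroke model and its sham no difference passed (adjusted p = 0.661 and 0.873 over 9 tests, exact permutation tests). miR-34b-3p, the neighbour of miR-34c, had 23 counts in MCAO and 13 in MCAO_Sham, a CPM ratio of 1.33 with an interval of 0.646 to 2.86, and miR-449a-5p, of the same seed family, had 0 counts in all 25 libraries.

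If the effects between MCAO and MCAO_Sham were counting noise alone, the arms of one hairpin would move independently. Across 26 hairpins with both arms kept, the log2 fold changes of the 5p and 3p arms had a Pearson correlation of 0.715 and a Spearman correlation of 0.640 (permutation p = 6e-05, adjusted p = 0.000158 over 7 comparisons), and 18 hairpins had the same sign in both arms. In the other comparisons the Pearson correlation ranged from 0.393 to 0.714. Hairpins are not independent replicates, and variation shared by the arms within a library, whatever its source, gives the same pattern, so the test argues against counting noise alone and says nothing about the groups.

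On the first principal component of the kept miRNAs, with 27.9% of the variance, MCAO 2 lay at one end (-12.8) and Naive 3 at the other (5.64). MCAO 5 lay at -0.479, the MCAO library nearest to the MCAO_Sham libraries, which ranged from -0.200 to 3.46.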
